A study of Mus musculus with 10 samples.

How the data were processed

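RNA from mouse brain tissue was profiled on 10 arrays, 5 ipsilateral and 5 contralateral to a controlled cortical impact. Per the labels' protocols, tissue was taken 7 days after a 2 mm impact and flash frozen, total RNA was isolated with a Qiagen RNeasy kit, and single-stranded cDNA was prepared with the Affymetrix WT PLUS kit. The analysis started from the deposited log2 signals, 1 column per array, which the authors made with Transcriptome Analysis Console 4.0, per the submitters' processing notes. The log2 scale was read from the values, which had 2 decimals and a range of 1.97 to 19.93. The background correction, the normalization, the summarization and the genome build were not given in the sources used here. The medians of the arrays over all rows lay between 4.71 and 4.84, so the distributions were not identical between arrays. Every ipsilateral median (4.79 to 4.84) was above every contralateral one (4.71 to 4.77). An offset between arrays can therefore not be told apart from side. All columns of the table were mapped to samples by their labels. No pair of arrays held identical values. The labels gave no batch, slide or scan date, and batch effects were therefore not tested.

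The table had 65956 rows. The array annotation used here listed 32750 of them, of which 30604 named 1 gene symbol and 2146 several, and 33206 rows were unnamed here. Of the 1-symbol rows, 22818 matched a gene by Entrez identifier in the RefSeq gene table of GRCm38.p6, and 827 symbols were updated from it. That table served for names and gene classes alone, and no coordinates were used. Rows that named several symbols were left out. For genes with several rows, the row with the highest mean over all 10 arrays was kept, which left out 462 rows and gave 30142 genes.

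The comparison was ipsilateral minus contralateral, fitted to all 10 arrays in limma 3.58.1 (R 4.3.3, statmod 1.5.0) with lmFit and eBayes at their default settings and no covariates. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. Values are mean log2 signal ± SD, fold changes are differences of log2 means with the SE of the fit, and unless stated otherwise an adjusted p is that of this fit. In advance, 32 lists of cell-type markers and pathways were fixed. They held 424 genes, of which 382 had a row that named them alone. Each list was tested with limma's camera (preset inter-gene correlation 0.01, Benjamini-Hochberg over the 32 lists). Alternatives were camera with an estimated correlation, fry, and an exact permutation test of the list score (the mean log2 signal of the measured members) over the 252 splits of 10 arrays into 5 and 5, whose smallest two-sided p is 0.00794. Some genes are in more than 1 list.

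The genes to be named were also fixed beforehand. They were the 8 largest rises and 8 largest falls among called genes with non-overlapping groups, leaving out symbols that begin with Gm and digits or LOC or end in Rik, and immunoglobulin or T cell receptor segments, and in each list the 2 members with the largest absolute moderated statistic. In addition, a list's most extreme called member against the majority of the list was named. Called list members outside this rule were named because a list held 5 or fewer of them, and Gad1, Gad2 and Fos were named after their values had been seen.

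The steps were tested on simulated data with the means and spreads of the real arrays and 200 changed genes among 30142. For the ipsilateral against contralateral comparison, 52.2% of the genes changed by 0.5 on the log2 scale were recovered, 88.1% of those changed by 1 and 95.5% of those changed by 2. A complement list shifted by 0.5 was called, and 0 of the 31 other lists were. The simulated noise was independent between genes, so false list calls from genes that vary together were not tested by it. Of 100 splits of the real arrays, drawn from 126 distinct ones with the real one included, 97 of the others called at least 1 list in camera.

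Alternatives chosen before the data were examined were a fixed or random block for the replicate number, trended and robust variance, array weights, quantile, median and cyclic loess scaling, 2 filters on dim genes (the lowest 25% and 50% by mean), the mean of a gene's rows, every row of the table, the level of Xist as a covariate because the labels name both sexes, a threshold of 0.01, and each array left out in turn. Xist turned out low on all 10 arrays (4.53 to 4.67), so that covariate carried no difference of sex. Added after seeing the data were protein-coding genes alone, the omission of the arrays numbered 2 and 4 on both sides, and array weights estimated per side.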

Results

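Gene expression was measured in mouse brain 7 days after controlled cortical impact, a model of brain injury in which a piston strikes the exposed cortex of one hemisphere. The impact was 2 mm deep, and per the labels the mice were adults of both sexes, 8 to 12 weeks old. The arrays did not show both sexes: Xist stood between 4.53 and 4.67, below every array's median, and the Y-linked genes Kdm5d, Eif2s3y and Uty between 7.75 and 8.88 on all 10 arrays. Tissue at the impact site (ipsilateral, 5 samples) was compared with the corresponding region of the other hemisphere (contralateral, 5 samples). Each sample was hybridised to 1 whole-transcript array. The labels call the samples biological replicates, and the number of arrays limits the precision of every comparison. Deposited log2 signals ran from 1.97 to 19.93, and the median signal per array lay between 4.71 and 4.84. After the choice of 1 probe set per gene, 30142 genes were tested. Arrays of the same side correlated across genes at 0.990 to 0.996 ipsilaterally and 0.992 to 0.997 contralaterally, and arrays of opposite sides at 0.988 to 0.995. The median SD per gene was 0.155 on the ipsilateral side and 0.124 on the contralateral side, and 63.6% of genes varied more on the ipsilateral side.

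The comparison asked which transcripts differed between the impact site and its counterpart in the other hemisphere. The samples held no sham-operated or unimpacted mice, so a change of the contralateral side itself was not measured. More genes fell than rose in ipsilateral tissue: 1305 genes were lower and 369 were higher, and 151 of the lower and 54 of the higher genes differed by at least 2-fold. The largest rises among called genes whose groups did not overlap were Tmem255a, which encodes a transmembrane protein (11.48 ± 0.48 against 8.75 ± 0.60, mean ± SD, n = 5 per side), Nnat, an imprinted gene encoding neuronatin (11.84 ± 0.80 against 9.27 ± 0.84), and Trh, the precursor of thyrotropin-releasing hormone (6.82 ± 1.34 against 4.57 ± 0.24). Their log2 fold changes were 2.73 ± 0.30 (SE), 2.57 ± 0.45 and 2.25 ± 0.53. The largest falls were Arc, an activity-induced regulator of synapses, at -3.44 ± 0.56, the voltage-gated potassium channel gene Kcnh5 at -3.01 ± 0.59, and Smim43, which encodes a small membrane protein, at -2.44 ± 0.27. Arc stood at 10.02 ± 1.35 ipsilaterally and 13.46 ± 0.52 contralaterally.

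**Figure D1:**
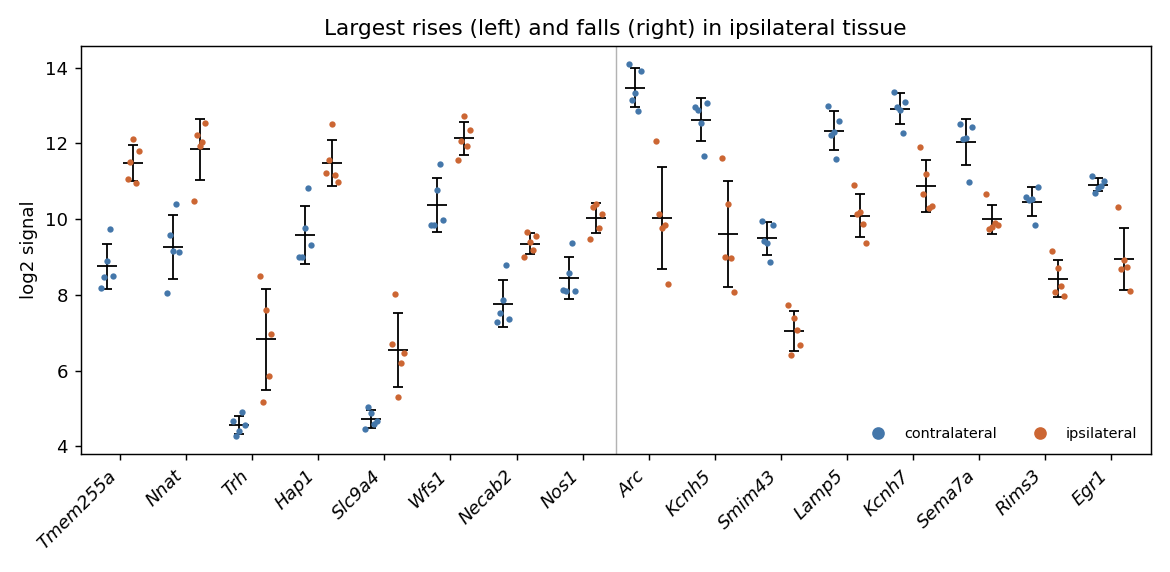
Log2 signal (vertical axis) of the 8 largest rises and the 8 largest falls (horizontal axis) on each of the 10 arrays. Points are single arrays, horizontal bars are means and error bars are SD (n = 5 per side). In each gene shown the 2 groups of points do not overlap, and Tmem255a rose by 2.73 while Arc changed by -3.44 on the log2 scale.

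The other 5 genes among the leading rises were Hap1, whose product binds huntingtin (1.91, adjusted p = 0.0164), the sodium-proton exchanger Slc9a4 (1.82, adjusted p = 0.0239), the endoplasmic reticulum membrane gene Wfs1 (1.76, adjusted p = 0.0113), the neuronal calcium-binding gene Necab2 (1.59, adjusted p = 0.00699) and neuronal nitric oxide synthase, Nos1 (1.57, adjusted p = 0.00751). The other 5 leading falls were Lamp5, a membrane gene that marks a class of cortical interneurons (-2.24), the axon-guidance gene Sema7a (-2.04), the potassium channel gene Kcnh7 (-2.04), the presynaptic gene Rims3 (-2.03) and the immediate early transcription factor Egr1 (-1.96). Adjusted p of the 8 falls ran from 0.00123 (Smim43) to 0.0148 (Kcnh5) in limma. Non-overlapping groups were found for 2185 genes (7.25%), where chance gives 0.794%, and for 1410 of the 1674 called genes. The contralateral means of Trh (4.57) and Slc9a4 (4.73) lay below or within the range of the array medians (4.71 to 4.84), where signal above background was not shown, so the size of these rises and their place among the largest are not settled. At an unadjusted p under 0.05, 6420 genes differed.

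The balance of rises and falls depended on scaling and on single arrays. Rises made up 22.0% of calls on the deposited values, and 8.13% (232 higher, 2623 lower) when each array was centred on its median. Every ipsilateral array had a higher median (4.79 to 4.84) than every contralateral one (4.71 to 4.77), so the balance is not settled. The replicate number as a fixed block left 177 genes higher and 769 lower, and Trh did not pass with it (adjusted p = 0.0546). The count of higher genes was 760 without ipsilateral replicate 1, 183 without ipsilateral replicate 5, and 111, 185, 124 and 173 without contralateral replicates 1, 2, 3 and 5. The count of lower genes was 740, 795 and 835 without contralateral replicates 1, 3 and 5. The count of genes at least 2-fold higher was 149, 35 and 30 without ipsilateral replicates 1, 3 and 5 and 15, 21, 83 and 26 without contralateral replicates 1, 3, 4 and 5. Without single arrays, the calls of Hap1 (contralateral replicate 1, adjusted p = 0.0509), Slc9a4 (ipsilateral 5, contralateral 1, 3 and 5, up to 0.0674) and Trh (ipsilateral 3 and 5, contralateral 1, 2, 3 and 5, up to 0.0839) ended. Without the arrays numbered 2 and 4 on both sides, a setting chosen after seeing the data that left 3 arrays per side, 77 genes were higher and 289 lower, and the calls of Arc (adjusted p = 0.108), Egr1 (0.150), Kcnh5 (0.168), Kcnh7 (0.0661), Nnat (0.0705), Hap1 (0.0639), Slc9a4 (0.109) and Wfs1 (0.0545) ended.

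Some neuronal genes fell at the impact site, and most of those measured did not pass the test. Of 14 measured genes of excitatory neurons and glutamate synapses, 4 fell and 1 rose: the calmodulin-binding synaptic gene Nrgn (-1.39 ± 0.17), the cortical transcription factor Tbr1 (-1.09 ± 0.13), the postsynaptic scaffold Homer1 (-1.44 ± 0.22) and the NMDA receptor subunit Grin2a (-0.84 ± 0.16) fell, while the AMPA receptor subunit Gria1 rose by 0.84 ± 0.12. Of 11 measured genes of inhibitory neurons and GABA synapses, 4 fell and none passed the test upward. These were the interneuron genes Pvalb (-1.84 ± 0.26) and Vip (-1.12 ± 0.18), the potassium channel Kcnc1 (-0.58 ± 0.13) and the GABA receptor subunit Gabrb2 (-0.43 ± 0.11). The GABA-synthesising enzymes Gad1 (0.21) and Gad2 (0.60) did not pass the test. Of 11 activity-dependent immediate early genes, 4 fell: Arc, Egr1 (8.94 ± 0.83 against 10.90 ± 0.17), Egr4 (-0.61 ± 0.12) and the phosphatase gene Dusp1 (-1.25 ± 0.23). The remaining 7 had negative fold changes that did not pass, such as Fos at -1.47 (adjusted p = 0.0672). Ipsilateral replicate 1 had an immediate early gene score of 9.22, inside the contralateral range of 8.96 to 9.63, and the other 4 ipsilateral arrays lay between 7.19 and 7.93.

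Adjusted over the list alone, 6 excitatory genes were lower and 1 higher, 4 inhibitory genes were lower, and 8 immediate early genes were lower. In camera with a preset inter-gene correlation of 0.01, the excitatory list (adjusted p = 0.000781), the inhibitory list (0.00249) and the immediate early list (6.11e-07) shifted downward. None of these 3 shifts held with an estimated correlation (adjusted p = 0.427 for each). The mean list scores differed by -0.37 (excitatory), -0.38 (inhibitory) and -1.27 (immediate early), with exact two-sided permutation p of 0.00794, 0.0794 and 0.0238 and adjusted values of 0.0564, 0.115 and 0.0635. Without the arrays numbered 2 and 4, the calls of Arc, Egr1 and Vip ended (adjusted p = 0.108, 0.150 and 0.119), and so did the shift of the inhibitory list (0.0588).

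Among 12 genes of neuronal injury and the integrated stress response, 2 rose and 1 fell. The growth-associated transcription factor Sox11 rose by 0.89 ± 0.13 and Jun by 0.75 ± 0.18, while the stress-induced gene Gadd45a fell by 0.41 (adjusted p = 0.0186, and 0.0570 and 0.0531 without contralateral replicates 1 and 5, and 0.106 without the arrays numbered 2 and 4). Adjusted over the list alone, 3 were higher and 1 lower. The list did not shift in camera (adjusted p = 0.237), except without contralateral replicate 4 (0.0323). Markers of other brain regions differed unevenly. Of 7 hippocampal genes only Wfs1 passed the test, at 12.13 ± 0.43 against 10.37 ± 0.71, and Fibcd1 had a log2 fold change of 0.95 (adjusted p = 0.136). Of 9 thalamic genes, Ramp3, a receptor-associated protein, fell by 0.91 (adjusted p = 0.000109) and the nuclear receptor Rora by 1.27 (adjusted p = 0.00161). Rora was read from the brightest of its 3 probe sets, and its log2 fold change was -0.65 with their mean, while without the arrays numbered 2 and 4 its call ended (adjusted p = 0.0550). Neither list shifted in camera (adjusted p = 0.275 and 0.421). The thalamic list had a median log2 fold change of -0.02, a downward direction in camera and a score difference of 0.18. Adjusted over the list alone, 1 hippocampal gene was higher, and 2 thalamic genes were higher and 2 lower. None of the 7 striatal genes passed, with Penk, an opioid precursor, at 1.22 (adjusted p = 0.0589) and the dopamine receptor gene Drd2 at 0.84 (adjusted p = 0.157), and 1 was higher adjusted over the list alone. The striatal list shifted upward in camera (adjusted p = 0.0169), but not without ipsilateral replicate 3 (0.144) or with an estimated correlation (adjusted p = 0.458).

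Position markers composed after the leading genes had been seen, but before their own values were, also moved with side. The mean score of 15 neocortical layer genes was 8.53 ± 0.08 ipsilaterally and 8.99 ± 0.07 contralaterally, and that of 15 ventral forebrain genes was 8.72 ± 0.26 and 8.13 ± 0.24. In both lists no ipsilateral array overlapped a contralateral one (exact two-sided permutation p = 0.00794, the smallest that 252 splits allow, and 0.0106 after adjustment over 4 such lists). Of the neocortical genes 7 fell and 4 had positive fold changes. Of the ventral forebrain genes 3 rose and 2 had negative fold changes. In camera with an estimated correlation the neocortical list shifted (unadjusted p = 0.000716) and the ventral forebrain list did not (unadjusted p = 0.0885).

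Most glial and immune genes listed had a higher mean at the impact site, but few passed the test one by one. Gfap, the astrocyte filament protein, stood at 15.73 ± 1.29 against 13.66 ± 0.93 (log2 fold change 2.07, adjusted p = 0.0814). C1qb, a complement subunit, stood at 12.93 ± 1.11 against 11.10 ± 0.61 (1.83, adjusted p = 0.0580). Of 12 homeostatic astrocyte genes the water channel Aqp4 rose, by 0.95 ± 0.18, and the glutamate transporter Slc1a3 had a fold change of 0.47 (adjusted p = 0.0623). Of 15 phagolysosome genes Grn, the lysosomal glycoprotein progranulin, rose by 1.48 ± 0.35, and the protease Ctsh had a fold change of 1.00 (adjusted p = 0.0842). Of 13 genes of infiltrating monocytes and macrophages, the scavenger receptor Cd163 rose by 0.47 ± 0.10. Of 15 chemokine genes the receptor Cxcr4 rose by 0.98 ± 0.25, from a contralateral mean of 4.58 that lay below every array's median, so that the size of its rise is not settled, and of 14 genes of oxidative stress and iron handling the cystine transporter Slc7a11 rose by 1.13 ± 0.29.

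**Figure D2:**
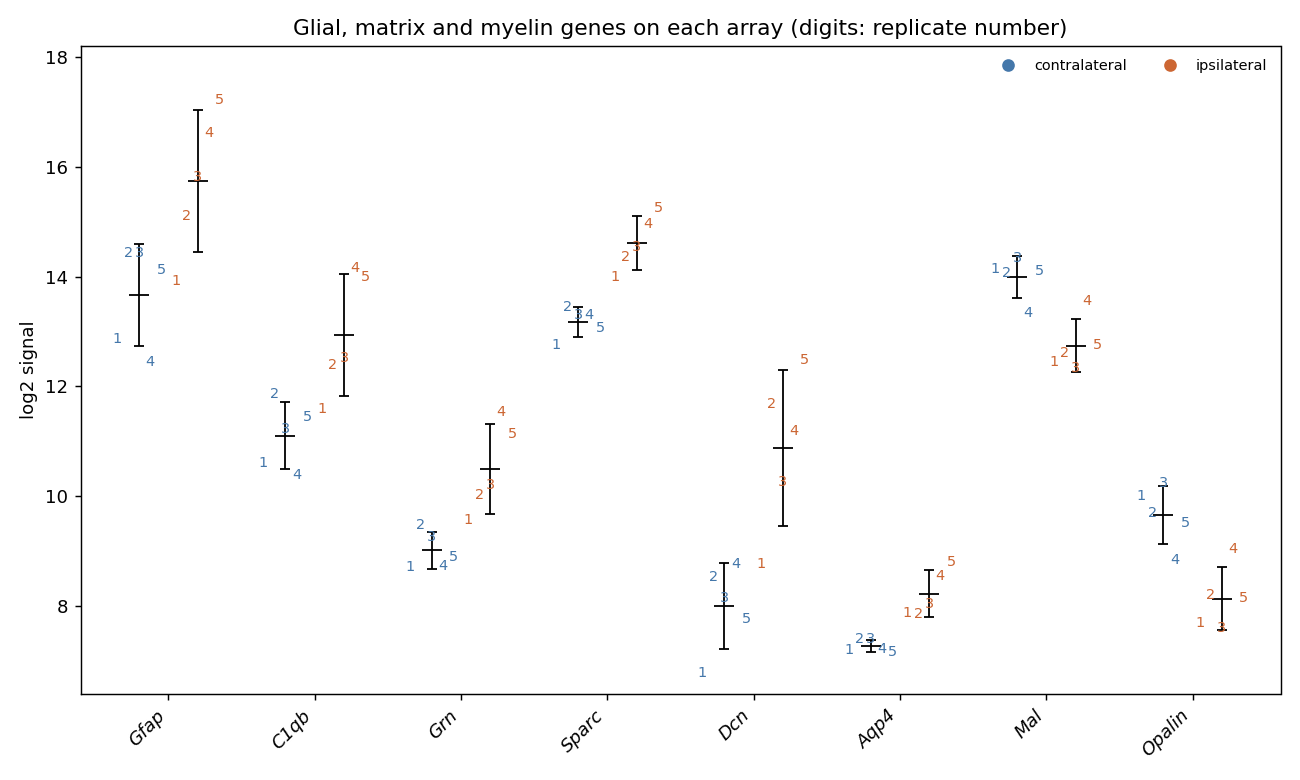
Log2 signal (vertical axis) of 8 glial, matrix and myelin genes (horizontal axis) on each array, with digits at the value of each replicate number. Horizontal bars are means and error bars are SD (n = 5 per side). For Gfap, the ipsilateral values ran from 13.91 to 17.21 and the contralateral values from 12.45 to 14.43.

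None of the 13 reactive astrocyte, 12 complement, 17 disease-associated microglia, 11 homeostatic microglia, 16 type I interferon, 13 antigen presentation, 16 inflammasome, 13 lipid efflux or 12 neutrophil genes passed over all genes tested. Adjusted over the list alone, 11, 11, 3, 5, 2, 11, 3, 4 and 0 of them were higher. The corresponding numbers were 3 for phagolysosome, 2 for monocytes and macrophages, 1 for chemokines, 1 for oxidative stress and iron handling, and 3 higher and 1 lower for homeostatic astrocytes. The members with the strongest statistics, none of which passed, included Aspg (0.30), the lipoprotein Apoe (0.70), the integrin Itgax (0.36), the purinergic receptor P2ry13 (0.72), Olfml3 (0.42), the interferon-induced Ifitm3 (1.67) and Irf9 (0.69), and the class I subunit B2m (1.37). Others were H2-Eb1 (0.41), Casp1 (0.90), Tlr4 (0.65), the lipid-droplet gene Plin2 (0.93), Cd36 (0.95), C3ar1 (1.54), F13a1 (0.77), Cxcl10 (0.50), Cp (0.82), Csf3r (0.75) and Camp (0.13), with adjusted p from 0.0512 (Irf9) to 0.232 (Camp).

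In camera with the preset correlation, 13 of these 14 lists shifted upward. Adjusted p was 4.99e-06 for reactive astrocytes and for interferon, 5.49e-06 for antigen presentation, 1.22e-05 for complement and phagolysosome, 2.19e-05 for disease-associated microglia and 0.000160 for homeostatic microglia. It was 0.000606 for monocytes and macrophages, 0.000744 for oxidative stress and iron handling, 0.00103 for lipid efflux, 0.00263 for chemokines, and larger but under the threshold of 0.05 for the inflammasome and neutrophil lists. The homeostatic astrocyte list did not shift (0.274). No upward shift held with an estimated correlation (adjusted p = 0.458 for the inflammasome list and 0.427 for each of the other 12). The neutrophil shift ended without ipsilateral replicate 5 (0.0803) and without the arrays numbered 2 and 4 (0.0531). Both mean neutrophil scores (4.53 ipsilaterally and 4.32 contralaterally) lay below every array's median, where signal above background was not shown. Ipsilateral replicates 4 and 5 had the 2 highest scores of all 10 arrays for complement (8.70 and 8.87), while ipsilateral replicate 1 (7.13) lay within the contralateral range of 6.63 to 7.40.

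**Figure D3:**
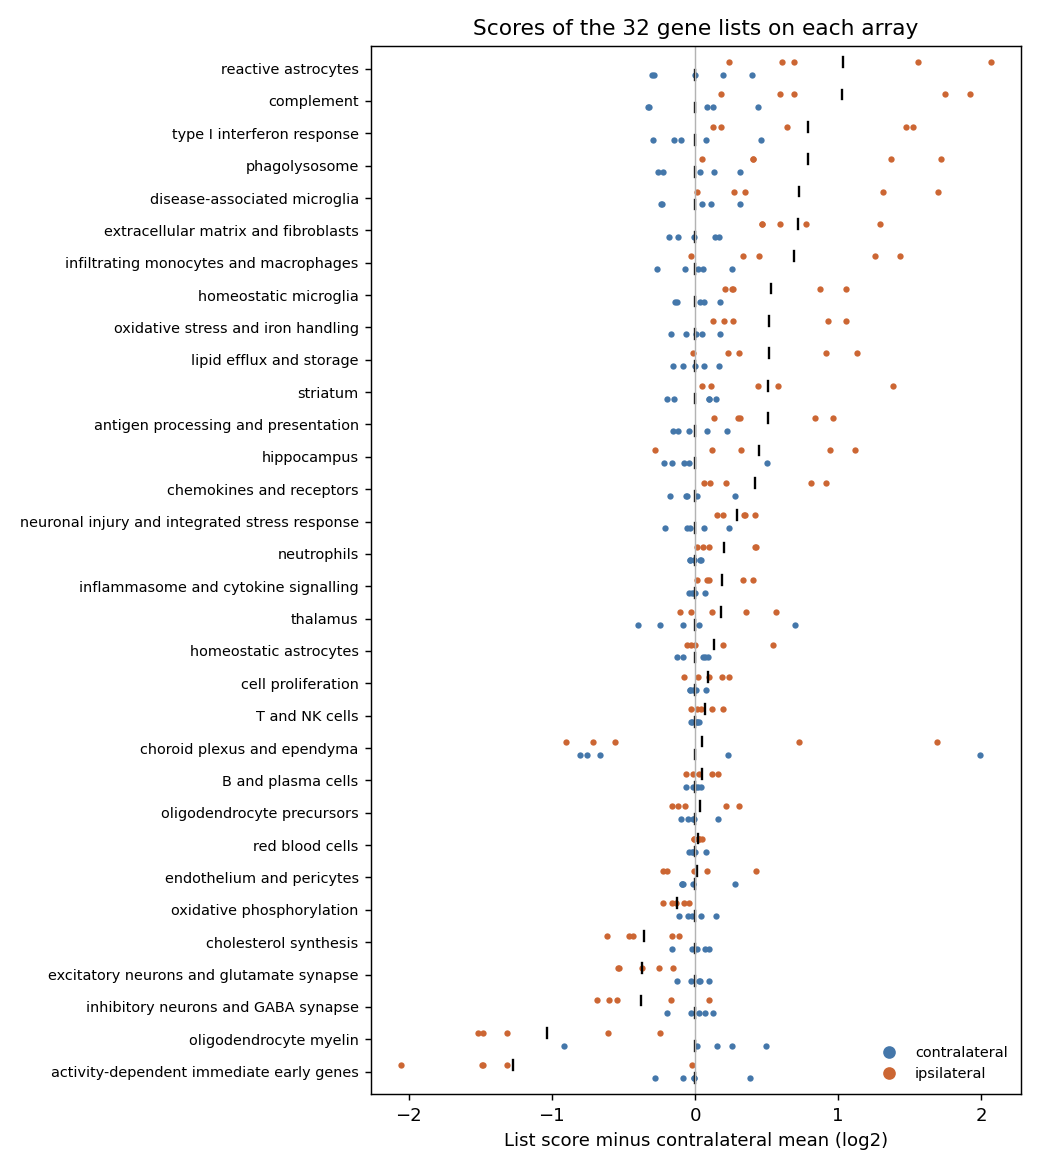
Scores of the 32 gene lists (vertical axis) on each of the 10 arrays, as the mean log2 signal of the members minus the contralateral mean of that list (horizontal axis). Points are arrays, and short vertical bars are the means of the 5 arrays of a side. The differences of the means run from 1.03 for reactive astrocytes to -1.27 for immediate early genes.

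The Cd163, Grn, Cxcr4 and Slc7a11 calls each depended on single arrays, and they and that of Aqp4 ended without the arrays numbered 2 and 4 (adjusted p from 0.115 to 0.169). With quantile scaling Cd163, Cxcr4 and Slc7a11 did not pass (0.0520 to 0.0765). Nor did Cd163, Grn, Cxcr4 or Slc7a11 with the replicate number as a fixed block (0.0507 to 0.139). Cd163 no longer passed without ipsilateral replicate 4 or contralateral replicate 1, 3 or 5 (adjusted p up to 0.0663), nor Grn without ipsilateral replicate 5 or contralateral replicate 1, 3, 4 or 5 (up to 0.0879). Of the 10 fits that each left out 1 array, Cxcr4 passed only without ipsilateral replicate 3 or contralateral replicate 2 (otherwise up to 0.113), and Slc7a11 only without ipsilateral replicate 1 or contralateral replicate 4 (otherwise up to 0.112). Lymphocyte and proliferation genes gave no called member. None of 13 genes of T and NK cells, 9 of B and plasma cells or 17 of cell proliferation passed, over all genes or over the list alone, with values such as Cd4 at 0.20, Il2rb at 0.14, Mzb1 at 0.22, Cd22 at 0.26, Aurka at 0.19 and Bub1 at 0.17. Camera adjusted p was 0.252, 0.722 and 0.0698 for these 3 lists, and 0.0394, 0.00970 and 0.0434 for proliferation without ipsilateral replicates 2 and 3 and contralateral replicate 5. Mean scores, ipsilateral and contralateral, were 4.33 and 4.26 for T and NK cells and 4.32 and 4.27 for B and plasma cells. These lay below every array's median, where signal above background was not shown, so the absence of lymphocyte calls does not settle whether lymphocytes differed.

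Several extracellular matrix genes rose at the impact site. Of 16 measured matrix and fibroblast genes, 5 rose, all 16 had positive fold changes, and 13 were higher adjusted over the list alone. Sparc, a collagen-binding matrix protein, stood at 14.61 ± 0.49 against 13.17 ± 0.27 (log2 fold change 1.44, adjusted p = 0.00480). Dcn, the proteoglycan decorin, rose by 2.88 ± 0.63, tenascin C (Tnc) by 0.88 ± 0.21, and the collagen chains Col1a1 and Col6a1 by 0.80 ± 0.19 and 0.62 ± 0.16. The list shifted upward in camera (adjusted p = 5.60e-08) but not with an estimated correlation (adjusted p = 0.427). Its score differed by 0.72, and every ipsilateral array was above every contralateral one (exact two-sided permutation p = 0.00794, adjusted 0.0564). The groups of Dcn and of Tnc values overlapped, and the call of Dcn ended without ipsilateral replicate 2, 4 or 5 or contralateral replicate 1, 3 or 5 (adjusted p up to 0.0672). Without the arrays numbered 2 and 4, the calls of Dcn and Sparc ended (adjusted p = 0.185 and 0.0761). No gene of the endothelium and pericyte (15), red blood cell (3) or choroid plexus and ependyma (8) lists passed, over all genes or over the list alone. Examples were the VEGF receptor Flt1 at -0.36, the transporter Slco1c1 at -0.38, Alas2 at 0.03, Epb42 at 0.03, Tmem212 at 0.27 and Rarres2 at 0.16. Camera adjusted p for these lists was 0.804, 0.820 and 0.575. Both mean red blood cell scores (4.19 ipsilaterally and 4.17 contralaterally) lay below every array's median. The endothelial list had a median of 0.03 and a score difference of 0.02 with a downward direction in camera. Choroid plexus scores were 8.30 and 7.34 on ipsilateral replicates 2 and 4 and 8.60 and 6.84 on contralateral replicates 2 and 4, against 5.71 to 6.06 on the other 6 arrays.

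A few myelin and cholesterol synthesis genes fell at the impact site. Of 11 measured oligodendrocyte myelin genes, 2 fell and all 11 had negative fold changes. Opalin, an oligodendrocyte membrane protein, fell by 1.52 (8.13 ± 0.57 against 9.66 ± 0.54). Mal, a myelin proteolipid, had a mean of 12.74 ± 0.49 ipsilaterally and fell by 1.26 (adjusted p = 0.0148). The groups of Opalin and of Mal values overlapped. Neither gene passed with the replicate number as a fixed block (adjusted p = 0.0933 for Opalin and 0.0856 for Mal). Adjusted over the list alone, 9 myelin genes were lower. None of 9 oligodendrocyte precursor genes passed, over all genes or over the list alone, with Lhfpl3 at 0.81 and Bcas1 at -0.32. Of 10 cholesterol synthesis genes, 2 fell, Idi1 by 0.65 (adjusted p = 0.0111) and Fdft1 by 0.46 (adjusted p = 0.00943), and 6 were lower adjusted over the list alone. Of 15 oxidative phosphorylation genes 1 fell, the complex I subunit Ndufs1, by 0.27 (adjusted p = 0.0387), and 1 was lower adjusted over the list alone. Another subunit, Ndufv1, had a fold change of -0.28 (adjusted p = 0.0855).

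The myelin (adjusted p = 6.11e-07), cholesterol synthesis (1.22e-05) and oxidative phosphorylation (0.00249) lists shifted downward in camera, and none did with an estimated correlation (adjusted p = 0.427 for each). The precursor list did not shift (0.856), with a median of -0.06, a downward direction in camera and a score difference of 0.03. Ndufs1 passed only without ipsilateral replicate 1 among the 10 fits that left out 1 array (otherwise up to 0.0986), and Opalin did not pass without contralateral replicate 1 (0.0526). Without the arrays numbered 2 and 4, the calls of Idi1, Fdft1 and Ndufs1 ended (adjusted p = 0.167, 0.152 and 0.271). Idi1 and Ndufs1 also did not pass with the replicate number as a fixed block (0.0572 and 0.109). Contralateral replicate 4 had a myelin score of 10.13, below the 11.06 to 11.54 of the other contralateral arrays and inside the ipsilateral range of 9.53 to 10.80.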

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

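Each array was compared with the other 4 of its side for 32 list scores and 78 named genes, and 10 values stood apart by Dixon's ratio (above 0.71), a rule that flags about 1 in 20 groups by chance. No test in this part was added after the results were seen. On the contralateral side, replicate 2 had scores of 8.64 for endothelium and pericytes (others 8.27 to 8.35) and 7.68 for hippocampus (others 6.96 to 7.14). Contralateral replicate 4 had 4 of the 5 contralateral gene values that stood apart (3.9 of 78 were expected by chance over the whole side). These were Cd36 at 5.84 (others 5.00 to 5.11), Mal at 13.33 (14.06 to 14.34), Pvalb at 7.48 (8.47 to 8.78) and Sema7a at 10.98 (12.10 to 12.52). The remaining one was Slc1a3 at 8.18 on contralateral replicate 1 (8.49 to 8.59). On the ipsilateral side, Sema7a stood at 10.66 on replicate 1 (others 9.75 to 9.90), Epb42 at 4.02 on replicate 2 (3.93 to 3.95) and H2-Eb1 at 5.77 on replicate 5 (5.14 to 5.23), against 3.9 expected by chance. No ipsilateral list score stood apart, where 1.6 were expected.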

How the results depend on the processing

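Protein-coding genes alone, the omission of arrays 2 and 4 on both sides and array weights per side were chosen after seeing the data. Of 37 called named genes, none reversed, 24 lost the call under some setting, and 26 kept it in all 10 fits that left out 1 array. Without arrays 2 and 4, 21 lost it, and at a threshold of 0.01, 16. With Xist, Cd163, Cxcr4, Dcn, Grn, Ndufs1, Slc7a11 and Slc9a4 lost it, with quantile scaling Cd163, Cxcr4, Ndufs1 and Slc7a11, with cyclic loess Cd163, Cxcr4 and Ndufs1, with median centring and with trended and robust variance Cxcr4 and Slc7a11, and with weights per side Slc7a11. Of 78 named genes, 31 kept direction and side of the threshold in every setting with a value. The replicate number as a fixed block gave 177 higher and 769 lower genes (876 also called without it) and 35 at least 2-fold higher. With it, 9 called named genes did not pass: Cd163, Cxcr4, Grn, Idi1, Mal, Ndufs1, Opalin, Slc7a11 and Trh. The consensus correlation within numbers was 0.00683, and 1 of 5 ipsilateral arrays correlated best with its own number. Correlations over all genes do not decide whether same-numbered arrays share an animal. The sides were compared unpaired because the labels state no pairing. Array weights gave 656 higher and 96 at least 2-fold higher genes, median centring 232 higher and 2623 lower, the test of every measured probe set gave 251 at least 2-fold lower, a threshold of 0.01 gave 47 higher, 537 lower and 13 at least 2-fold higher, and the omission of arrays 2 and 4 gave 77 higher and 289 lower (fewer samples). Leaving out 1 array gave 111 to 760 higher, 740 to 1607 lower and 15 to 149 at least 2-fold higher genes.

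With an estimated correlation the adjusted p of all 21 called lists was 0.427, except 0.458 for inflammasome and striatum. In fry it was 0.0650 for cholesterol synthesis, extracellular matrix, inhibitory neurons and immediate early genes, 0.0664 for antigen presentation and excitatory neurons, 0.0793 for myelin, 0.0864 for homeostatic microglia, reactive astrocytes, complement and oxidative stress, 0.103 for neutrophils and interferon, 0.110 for monocytes, phagolysosome and oxidative phosphorylation, 0.112 for chemokines, 0.124 for disease-associated microglia, 0.132 for inflammasome and lipid efflux and 0.187 for striatum. In the exact permutation of list scores it was 0.0564 for homeostatic microglia, reactive astrocytes, complement, antigen presentation, inflammasome, oxidative stress, cholesterol synthesis, extracellular matrix and excitatory neurons, 0.0635 for phagolysosome and immediate early genes, 0.0726 for neutrophils and myelin, 0.0794 for monocytes and lipid efflux, 0.0847 for interferon and oxidative phosphorylation, 0.0967 for disease-associated microglia, chemokines and striatum and 0.115 for inhibitory neurons. For mixed directions, fry called 12 lists.

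List calls that ended in camera had adjusted p of 0.0717 for neutrophils with cyclic loess and 0.0891 without the dimmest 25% of genes. Without the dimmer 50% they were 0.176 for neutrophils and chemokines, 0.0773 for inflammasome, 0.0553 for inhibitory neurons and 0.0560 for oxidative phosphorylation. With Xist, which was low on all 10 arrays and so held no difference of sex, they were 0.113 for neutrophils and 0.0842 for inflammasome, and without arrays 2 and 4 0.0531 for neutrophils and 0.0588 for inhibitory neurons. Proliferation passed in protein-coding genes alone (0.0461). Leaving out 1 array gave ranges of 0.00883 to 0.0803 for neutrophils, 0.00201 to 0.144 for striatum, 0.00970 to 0.268 for proliferation, 0.0323 to 0.453 for neuronal injury, 0.159 to 0.844 for endothelium, 0.425 to 0.994 for precursors, 0.0753 to 0.909 for choroid plexus and 0.201 to 0.814 for thalamus.

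Directions that reversed were all of lists and genes that did not pass on the deposited values, and the values of lists are adjusted p and those of genes log2 fold changes. With quantile scaling they were B cells (0.994), endothelium (0.757), precursors (0.912), red blood cells (0.869), and the gene Alas2 (-0.0422) and gene Epb42 (-0.0118). With median centring they were endothelium (0.835), precursors (0.895), red blood cells (0.849), thalamus (0.997), Alas2 (-0.046) and Epb42 (-0.044), and with cyclic loess B cells and precursors (0.772 each), endothelium (0.717), red blood cells (0.747), Alas2 (-0.0321) and Epb42 (-0.012). Without the dimmer 50% they were endothelium and precursors (0.713 each), with Xist B cells (0.996) and thalamus (0.698), in fry endothelium (0.9746), in the exact permutation endothelium (0.909), precursors (0.855) and thalamus (0.499), and in protein-coding genes alone endothelium (0.986) and precursors (0.969). Without arrays 2 and 4 they were B cells (0.931), endothelium (0.202), red blood cells (0.978), thalamus (0.136) and Epb42 (-0.03). Alas2 ranged from -0.0165 to 0.08 and Epb42 from 0.01 to 0.05 when 1 array was left out.

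Without the dimmest 25%, the dim genes Cd4, Epb42, Il2rb and Mzb1 had no value. Without the dimmer 50%, the T and NK cell, B and plasma cell and red blood cell lists and the genes Alas2, Aspg, Bub1, Camp, Cd22, Cd4, Cxcl10, Cxcr4, Drd2, Epb42, H2-Eb1, Il2rb, Itgax, Mzb1 and Tmem212 had none. The settings with every row and with the stricter threshold gave gene counts but no lists. Apart from fewer genes or samples tested, the cause was not tested. Signal over background limits dim genes.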

Other observations

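The tests of ipsilateral replicate 1, potassium channels, the clock genes, shared replicate numbers, the contralateral arrays left out in turn and the 4 gene counts over other splits were chosen after the results were seen, and the neocortical and ventral forebrain lists were composed after the leading genes were known. Among 88 potassium channel genes (Kcn symbols), 23 were lower ipsilaterally and 4 higher, and between 21 and 29 were lower under the 3 other scalings. Of 14 circadian clock genes, 5 fell: Per1 (-0.68), Hlf (-1.05), Npas2 (-0.54), Cry1 (-0.51) and Cry2 (-0.52), while Arntl stood at -0.54 (adjusted p = 0.0630). The clock list score differed by -0.34 (exact two-sided permutation p = 0.00794), and by -0.33, -0.41 and -0.29 with quantile, median and cyclic loess scaling. Xist lay between 4.53 and 4.67 and the Y-linked genes Kdm5d, Eif2s3y and Uty between 7.75 and 8.88 on all 10 arrays. Ttr, which the choroid plexus expresses strongly, stood at 15.87 and 13.64 on ipsilateral replicates 2 and 4, at 16.54 and 12.66 on contralateral replicates 2 and 4, and between 5.83 and 7.55 on the other 6 arrays.

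Several neuronal genes were lower ipsilaterally, and a uniform loss or dilution of neurons was set against a different position of the dissected piece. The score of 15 neocortical layer genes fell by 0.45 and that of 11 pan-neuronal genes differed by -0.16 (exact permutation p = 0.103). Their difference of -0.30 (exact permutation p = 0.0159) argues against a uniform loss alone. The pan-neuronal genes were uneven: Rbfox3 (-0.54) and Stx1a (-1.03) fell, and 4 of the 11 had positive fold changes, none of which passed. A loss of neurons beside another cause is therefore not excluded. The score of 15 ventral forebrain genes was higher by 0.58 (exact permutation p = 0.00794), as a different position would give. Under the other 3 scalings it was higher by 0.56, 0.51 and 0.59. However, 3 of its genes passed one by one, and its camera p with an estimated correlation was 0.0885. The list was composed with the leading genes of the same arrays known, so its p is not independent of those genes. The neocortical fall was uneven: 7 genes passed, such as Rorb (-1.25) and Rspo1 (-1.01), and 4 had positive fold changes. Those 4 were Ntsr1 (0.26), Syt6 (0.16), Rprm (0.12) and Bcl6 (0.12), none of which passed. A candidate explanation is therefore that the ipsilateral pieces held less neocortex, or less of a part of it, and more ventral tissue. Loss of neocortex at the impact site and a different dissection would both give this, and the injury that the design names stays open, as untested.

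Ipsilateral replicate 1 had glial and immune scores near or within the contralateral range. A mislabelled side would place it nearer the contralateral mean, but 56.1% of 2367 genes called without it lay nearer the ipsilateral mean (Wilson 95% interval 54.1 to 58.1, with genes taken as independent, which they are not). This share was 73.4% to 94.2% for the other ipsilateral arrays and 2.59% to 32.4% for the contralateral arrays, each left out in the same way. Ipsilateral replicate 1 was also the only array whose mean correlation was higher with the other side (0.9922) than with its own (0.9917), but its neocortical layer score of 8.46 lay below the contralateral range of 8.91 to 9.06. A weaker change in all genes alike would give equal shares of the full change, and the medians were 66.8% in genes called lower and 9.88% in 101 glial and immune genes, but the latter share ran from 43.6% to 240% on the other ipsilateral arrays, so the gap lay within the spread between arrays and this stays open. The first values argue against a mislabelled side, and no biological explanation was tested.

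Among 1555 miRNA and snoRNA genes, 36 were higher and 3 lower ipsilaterally. An offset of whole arrays would end this after centring, but 27 were then higher and 10 lower (exact binomial p = 0.00763). That p treats genes of the same 10 arrays as independent. It does not measure the spread between samples, so an offset is not excluded by it. The mean level was 5.30 for miRNA and 7.72 for snoRNA genes, against 6.85 for protein-coding genes, so only the miRNA genes were dim on average. An effect of signal level would give as many calls in protein-coding genes of that level. On the deposited values 10000 matched sets held 12 to 29 higher calls (95% range), and 3 of the sets held as many. With quantile scaling the counts were 20 higher and 7 lower, and with cyclic loess 22 and 3. The matched range was not computed for the other scalings, and their counts of 27, 20 and 22 higher lie within it. The argument against signal level therefore holds on the deposited values alone. Whether the probe sets of these genes read small RNAs or longer transcripts of the same loci was not tested. No biological explanation was tested.

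The 23 lower potassium channel genes exceeded the 3 to 12 (95% range) of 10000 sets matched on level, which were not matched on how specific the genes are to neurons. Whether the clock was shifted between sides was not decided by Per1 at -0.682, since Arntl did not pass. Whether arrays of the same number shared an animal stayed open. For choroid plexus genes the labelled pairing was the closest of 120 (p = 0.00833 by exact permutation, the smallest that 120 pairings allow), but this was 1 of 34 gene sets compared, after its values were seen, and as the only set at that rank it did not pass an adjustment over 34 (0.283). The hippocampal and Y-linked sets ranked 5 (p = 0.0417 each by exact permutation). Of single genes, chosen after their values were seen, Eif2s3y ranked 1, Arntl 2, and Dbp, Ttr and Kcnj13 3, while Kdm5d ranked 66, Per1 63 and Uty 112. Across 1198 variable genes the labelled pairing ranked 20 of 120, with 10 genes against 124 for the best pairing, and across 584 genes it ranked 19, with 4 against 106.

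Of the 126 distinct splits of the 10 arrays, 100 were examined: the real one and others drawn at random. Of these 100, the real one included, 2 gave as many higher genes as the 369 observed (highest other 393). For lower genes, 1 gave as many as the 1305 observed (highest other 393). For genes at least 2-fold higher and at least 2-fold lower, 2 splits each gave as many as the 54 and 151 observed (highest other 310 for both). The other splits have no fixed direction, so the larger of their 2 directions was taken each time. Under 5% of splits were as large for each of these 4 counts, a test chosen after the results were seen and not adjusted over the 4. Only the 1305 lower genes exceeded every other split that was drawn. For the other 3 counts another split gave more genes, so chance is not excluded for them. The 393 and 310 genes came from the split that put ipsilateral replicates 1 and 4 with contralateral replicates 1, 3 and 5. Whether the samples have a structure besides side was not tested. For the 21 gene lists called, 19 splits gave as many (highest other 29), so chance is not excluded for the number of lists, and 97 of the other splits called at least 1 list.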
